A study of Homo sapiens with 12 samples.

How the data were processed

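RNA sequencing was available for 12 libraries from 2 human breast cancer cell lines, MDA-MB-231 and MCF7. Each cell line had 3 libraries from cells exposed to carbon monoxide (CO) at 250 ppm for 16 h and 3 libraries from cells kept in control air. Per the labels' protocols, the control condition was an ordinary culture incubator with 5% carbon dioxide, so the exposure to CO also meant another enclosure. No carbon dioxide level is recorded here for the CO condition. RNA was purified with a column kit, and polyadenylated RNA was made into stranded libraries that were read as paired ends of 50 bp, per the labels. The puromycin added to the medium of the MCF7 cells was not added to that of the MDA-MB-231 cells, per the labels.

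Counts per gene symbol were deposited as raw whole numbers, with no normalization by the authors. The authors also deposited FPKM values, that is fragment counts scaled by transcript length and by library size, in a second table that gives a genomic interval for each entry. The submitters' processing notes name bcl2fastq 2.19, cutadapt, TopHat2 2.0.11, Cufflinks 2.1.1 and HTSeq 0.6.1 and the build hg19, also called GRCh37. Which tool made which table, whether counting used the strand, and the annotation release are not given in the sources used here. Reads shared by near-identical genes, by overlapping genes or by a gene and its antisense partner can therefore be split in a way that is not known. Among the genes named, this concerns at least the overlapping intervals of C7orf29, PRDX1, SLC48A1, AHRR, POR, PFKM, HSPD1, HSPE1, CCNA2, DHFR, KRT8 and G6PD. It also concerns the close relatives or copies of KRTAP2-3, ALPP, KRT17 and HSPA1A. This set of genes with relatives or copies may be incomplete. The count table holds 23686 gene symbols and the FPKM table has 19312 entries, of which 426 share a symbol with another entry and were left out. Coordinates are those of the FPKM table on hg19, written with the first base as 1, and a few genes have no interval there. No symbol of a mitochondrially encoded gene occurs in the count table, so the list of 13 such genes was not tested.

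The total count per library ranged from 20534996 to 24388319, and the 10 most abundant genes took 4.88% to 5.50% of it. Genes were kept by the filterByExpr rule of edgeR with the 4 groups, which left 14803 genes, 62.5% of the table. Library sizes were scaled by TMM. One edgeR quasi-likelihood model (glmQLFit with robust estimation, glmQLFTest) held a mean for each of the 4 groups over all 12 libraries, with 8 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and standard errors of log2 fold changes were derived from the F statistic. Levels are given in CPM, that is counts scaled by library size with TMM factors, as mean ± SD over 3 libraries, and log2 fold changes as estimate ± SE. The comparisons were CO against control air in each cell line, the difference between those responses (MDA-MB-231 response minus MCF7 response, an interaction), and MDA-MB-231 against MCF7 in control air.

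The common biological coefficient of variation was 4.13%, and a chi-square statistic of the counts of replicate pairs was 1.69 to 5.26 per gene, above the value of 1 that sampling alone gives, so no library was a second copy of another. The labels number the replicates but do not say that they were separate cultures. P-values therefore measure only the spread between these samples, which may be technical.

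Gene lists were fixed before the data were examined. They comprise 29 lists with 584 different symbols, of which 569 occur in the count table, some under an older symbol, and 552 were tested. The lists cover NRF2 and antioxidant genes, heme, iron, aryl hydrocarbon receptor targets, cytochrome P450 enzymes, hypoxia, glycolysis, oxidative phosphorylation, protein folding and amino acid stress, heat shock, the cell cycle, p53, MYC, estrogen response, epithelial and mesenchymal genes, invasion and metastasis, NF-kB, interferon, immediate early genes, lipid synthesis, the circadian clock, histones, and markers of luminal and of mesenchymal basal breast cancer lines. Each was compared with all other genes by limma's camera on voom values with a preset inter-gene correlation of 0.01, adjusted over the 28 lists that could be tested. The same test with a correlation estimated from the data and limma's fry were run beside it. fry asks whether the members of a list move on balance one way and does not compare the list with other genes. The numbers of members past the threshold are given from the test of all genes and again adjusted over the list alone.

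The genes named in the text follow a rule fixed in advance. For each exposure comparison it takes the 8 largest rises and the 8 largest falls in log2 fold change among genes past the threshold, with a mean of at least 5 CPM over the 6 libraries of the cell line and no overlap between CO and control libraries. It also takes the 2 to 4 members of each list with the smallest p, and HMOX1, CYP1B1, MYC, ALAS1 and NQO1 whatever their values. For the interaction it takes the 5 largest differences in each direction among genes with a mean of at least 5 CPM over the 12 libraries. For the control cell lines it takes ESR1, GATA3, CDH1, VIM, CD44 and AXL. For many lists the text prints only some of the members so taken, and for some lists none. Which of them are printed was not fixed by the rule. A printed member can therefore go against the direction of most of its list.

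The edgeR step was tested on simulated data, with counts drawn from the means, dispersions and library sizes of these libraries, 200 genes changed in either direction and the DNA replication list raised 1.3-fold. For the MDA-MB-231 comparison, over 14610 genes, it recovered 77.6% of the genes changed 1.25-fold, 98.5% of those changed 1.5-fold and 100% of those changed 2-fold, and 3.24% of all calls were false. For the MCF7 comparison, over 14623 genes, the shares were 80.6%, 100% and 100%, and 5.80% of calls were false. Far fewer genes were changed in the simulation than were called in the data, 6563 in MDA-MB-231 and 5872 in MCF7. The shares were not split by expression level. They therefore describe the simulated setting only. They give no rate for genes with low counts or for data with so many changes. Alternatives chosen before the data were examined were DESeq2 size factors, no TMM, DESeq2 and limma-voom in place of edgeR, no filter and a stricter filter on low counts, the replicate number as a block, limma-trend on log2 of the deposited FPKM values plus a pseudocount of 1 or 0.1, fits of only the libraries compared, a minimum change of 1.5-fold, an unadjusted p under 0.01 for the genes called in both lines, and leaving out each library in turn. Chosen after seeing the data were a filter that keeps only genes with at least 1 CPM in at least 3 of the 6 libraries of the cell line, and a fit without the pair of libraries that held the most reads of the other cell line's genes. Software versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.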

Results

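Gene expression was measured by RNA sequencing in MDA-MB-231, a triple-negative breast cancer line with mesenchymal features, and MCF7, an estrogen receptor-positive luminal line. The labels give both lines as derivatives, MDA-MB-231/TGL and MCF7/TGL/pQ, without expanding the suffixes. Each line was grown either in control air or with CO, a gas that binds heme iron, at 250 ppm for 16 h, with 3 libraries in each of the 4 groups. Total counts were 21346015 to 23044849 in the MDA-MB-231 control libraries and 21164803 to 23175688 in the MDA-MB-231 CO libraries. In MCF7 they were 20534996 to 24388319 in control air and 21087594 to 24378674 with CO. Within each cell line the first principal component of log2 CPM separated the CO from the control libraries and held 55.6% of the variance in MDA-MB-231 and 52.9% in MCF7.

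The control libraries carried the expression profiles of the named lines. All 16 luminal markers were lower and all 16 mesenchymal basal markers higher in MDA-MB-231 than in MCF7 (camera adjusted p = 3.06e-08 and 1.81e-07, and adjusted p = 0.0833 for each with an estimated correlation). ESR1, which encodes estrogen receptor alpha, stood at 0.121 ± 0.0701 CPM in MDA-MB-231 and 174 ± 3.59 CPM in MCF7, a log2 difference of −10.44 ± 0.13. The luminal transcription factor GATA3 differed by −5.78 ± 0.056 and E-cadherin (CDH1) by −11.07 ± 0.19. Vimentin (VIM) was higher in MDA-MB-231 by 9.50 ± 0.092, the receptor tyrosine kinase AXL by 10.32 ± 0.070 and the hyaluronan receptor CD44 by 4.84 ± 0.048. Of 14803 genes, 12912 differed between the control lines, 6469 higher and 6443 lower in MDA-MB-231 (edgeR quasi-likelihood test, adjusted p under 0.05).

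A small amount of each line's specific transcripts was found in the libraries of the other. The 41 genes with at least 100 CPM in MCF7 and at least 200 times less in MDA-MB-231 had between 0.0923% and 0.146% of their MCF7 level in 5 MDA-MB-231 libraries, and 0.299% (95% Poisson interval 0.280 to 0.319) in the first MDA-MB-231 CO library. The 44 genes specific to MDA-MB-231 by the same rule had 0.118% to 0.169% of their MDA-MB-231 level in 5 MCF7 libraries and 0.200% (0.187 to 0.214) in the third MCF7 control library. These intervals cover counting error only. Of the 41 genes, 6 passed the threshold in MDA-MB-231, all higher with CO, and 3 did so without the first CO library. Of the 44 genes, 10 passed in MCF7, 9 of them lower with CO, and 1 did so without the third control library. The low levels of ESR1, CDH1, VIM and AXL in the line with less of them lie in or below the range of these shares, so the size of their differences is limited by this trace. Values near these shares are treated below as traces.

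**Figure D1:**
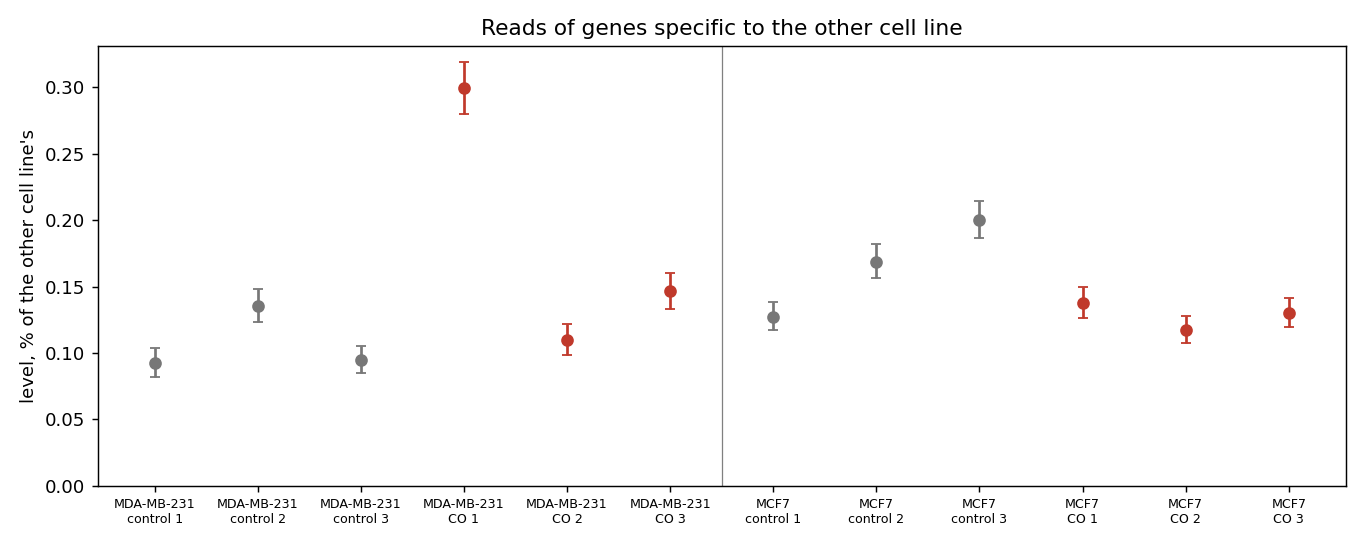
Level of genes specific to the other cell line in each library, as percent of their mean level in that other line, on a linear axis. Points are single libraries (grey, control; red, CO) and bars are 95% Poisson intervals, which cover counting error only. The first MDA-MB-231 CO library lies at 0.299% and the other 5 MDA-MB-231 libraries lie between 0.0923% and 0.146%.

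In MDA-MB-231, the largest rise with CO by the rule for named genes was in the serine protease family gene PRSS35 (hg19 chromosome 6, 84222194 to 84235421), from 0.565 ± 0.0687 to 18.5 ± 1.36 CPM, 32.3-fold. PTGS2 (chromosome 1, 186640944 to 186649559), which encodes cyclooxygenase-2, rose from 10.8 ± 0.493 to 56.7 ± 1.07 CPM, a log2 fold change of 2.39 ± 0.073. The alkaline phosphatase gene ALPP (chromosome 2, 233243348 to 233247599) rose by 2.08 ± 0.090, and the monocyte chemokine gene CCL2 by 1.99 ± 0.075. The aldose reductase gene AKR1B1 rose from 157 ± 4.41 to 615 ± 46.3 CPM. ATOH8, a basic helix-loop-helix transcription factor, C7orf29 and the adenosine receptor gene ADORA2A rose by 2.07, 1.99 and 1.92. By the same rule, the largest fall was in the hair keratin-associated gene KRTAP2-3, from 12.5 ± 1.78 to 2.82 ± 0.418 CPM. The xylulokinase gene XYLB followed at −1.53 ± 0.14 and the cell-cycle gene CDCA7 at −1.38 ± 0.079. TLN2 (talin 2), SDSL, the nucleolar gene NOC3L, PCYOX1L and FERMT1 (kindlin 1) fell by between 1.15 and 1.24 on the log2 scale. Adjusted p of these 16 genes lay between 1.24e-19 (PRSS35) and 1.07e-09 (XYLB). ALPP and KRTAP2-3 have near-identical relatives and the interval of C7orf29 overlaps that of another gene, so their counts are uncertain.

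The changes in MDA-MB-231 were numerous and mostly small. Of 14803 genes, 6563 passed the threshold, 3312 higher and 3251 lower with CO. At least 1.5-fold changes were found for 1226 of these genes, 658 higher and 568 lower, and at least 2-fold changes for 374. For 52.6% of the genes tested the 3 CO libraries lay on one side of the 3 control libraries, where chance gives 10%. Leaving out single libraries gave 5553 to 6051 calls, and without the pair of libraries with the most reads of the other line 5318 genes were called.

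Among the lists higher in MDA-MB-231, 12 of 19 tested members rose and 2 fell (13 and 2 adjusted over the list alone) for NF-kB and cytokine genes. NFKBIA (chromosome 14, 35870716 to 35873960), the inhibitor of NF-kB that NF-kB itself induces, rose from 41.7 ± 2.89 to 142 ± 9.79 CPM, and the chemokine genes CXCL1 and IL8 rose by 1.57 ± 0.12 and 0.81 ± 0.084 (camera adjusted p = 2.92e-04, and adjusted p = 0.333 with an estimated correlation). Of the invasion and organ-metastasis genes, 14 of 26 tested members rose and 4 fell (16 and 4 adjusted over the list alone), with the matrix gene TNC (tenascin C) at 1.27 ± 0.044, ID3 at 0.98 ± 0.074 and the cytokine gene IL11 at 0.65 ± 0.051 (adjusted p = 2.17e-04, and adjusted p = 0.307 with an estimated correlation). In the NRF2 and antioxidant list 13 of 23 tested members rose and 1 fell (13 and 1 adjusted over the list alone). The list's adjusted p was 2.32e-04, and adjusted p = 0.333 with an estimated correlation. The aldo-keto reductase gene AKR1C1 rose by 2.81 ± 0.18, from 1.22 ± 0.246 to 8.66 ± 1.76 CPM. Its mean level was too low for the rule that names the largest rises. Other members that rose were ME1 (0.64 ± 0.066), the quinone reductase gene NQO1 (0.36 ± 0.035) and the peroxiredoxin gene PRDX1 (0.30 ± 0.033). HMOX1 (chromosome 22, 35777060 to 35790207), the heme oxygenase gene whose product releases CO from heme, was the one member of that list that was lower, at 9.10 ± 0.282 and 7.48 ± 0.541 CPM, a log2 fold change of −0.28 ± 0.11 with adjusted p = 0.0372. That call was lost with DESeq2 (0.0694), with limma-voom (0.0538), without the first (0.0625) or the second (0.0963) control library and without the first (0.0575) or the third (0.151) CO library, and was 0.0641 without the pair of libraries with the most reads of the other line.

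Aryl hydrocarbon receptor targets and nuclear-encoded oxidative phosphorylation genes were also called higher in MDA-MB-231. Of the receptor targets 7 of 12 tested members rose and 2 fell (7 and 3 adjusted over the list alone), among them the receptor's repressor gene AHRR (0.67 ± 0.10), TIPARP (0.35 ± 0.056) and the cytochrome P450 gene CYP1B1 (chromosome 2, 38294746 to 38303323), which rose from 29.3 ± 1.29 to 64.7 ± 4.31 CPM (1.14 ± 0.13). The list's adjusted p was 0.0422, 0.0611 without the second control library, 0.0559 without the second CO library, and adjusted p = 0.451 with an estimated correlation. Of the oxidative phosphorylation genes 16 of 38 tested members rose and 4 fell (16 and 4 adjusted over the list alone), with small folds. SDHA (complex II) stood at 0.27 ± 0.039, COX4I1 (complex IV, the heme-containing oxidase) at 0.18 ± 0.035 and ATP5O at 0.20 ± 0.044, whereas SDHD was lower at −0.31 ± 0.051. The adjusted p was 0.0226, 0.0994 without the third control library, and adjusted p = 0.674 with an estimated correlation.

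DNA replication genes were the most uniformly lower group in MDA-MB-231. Of them 1 of 25 tested members rose and 18 fell (1 and 18 adjusted over the list alone). The ribonucleotide reductase gene RRM2 changed by −0.67 ± 0.037, the clamp loader gene RFC3 by −0.75 ± 0.060, DHFR (dihydrofolate reductase) by −0.50 ± 0.038 and the helicase gene MCM2 by −0.37 ± 0.042 (camera adjusted p = 1.56e-06, and adjusted p = 0.333 with an estimated correlation). In the MYC and ribosome biogenesis list 1 of 26 tested members rose and 15 fell (1 and 17 adjusted over the list alone). MYC itself was at −0.31 ± 0.042, and RRP9 and RRS1 at −0.52 ± 0.050 and −0.50 ± 0.066, with NOP2 the member that rose, at 0.32 ± 0.040 (adjusted p = 2.17e-04, and adjusted p = 0.451 with an estimated correlation). The heat shock list was mixed, as 4 of 19 tested members rose and 10 fell (4 and 12 adjusted over the list alone). HSP90AA1, HSPD1 and HSPE1 were at −0.40 ± 0.036, −0.39 ± 0.034 and −0.66 ± 0.078, and HSPH1, a cochaperone of the HSP110 family, was higher at 0.83 ± 0.069. The list's adjusted p of 0.0487 rose to 0.0611 without the second control library, to 0.105 without the second CO library and to 0.0917 when only genes expressed in MDA-MB-231 were tested, and adjusted p = 0.674 with an estimated correlation.

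The remaining lists were not called by camera in MDA-MB-231, although most held genes past the threshold in both directions. In brackets are the numbers adjusted over the list alone. For heme synthesis, transport and breakdown, 3 rose and 12 fell of 23 tested genes (3 and 12). ALAS1, the rate-limiting enzyme of heme synthesis, rose by 0.50 ± 0.046, and SLC48A1, a heme transporter, was at −0.65 ± 0.094. For iron handling, 4 rose and 5 fell of 16 tested genes (4 and 5), with the transferrin receptor gene TFRC at −0.29 ± 0.036, the aconitase and iron regulatory protein gene ACO1 at −0.43 ± 0.045 and SLC39A14 at 0.42 ± 0.043. For the hypoxia response, 7 rose and 7 fell of 24 tested genes (8 and 7), with ADM (adrenomedullin) at 0.95 ± 0.050 and the hexokinase gene HK2 at −0.73 ± 0.046. For glycolysis, 8 rose and 4 fell of 20 tested genes (9 and 4), with PKM at 0.34 ± 0.033 and PFKM at −0.39 ± 0.046. For the circadian clock, 4 rose and 5 fell of 18 tested genes (4 and 5), with ARNTL (BMAL1) at 1.09 ± 0.070, PER1 at 1.04 ± 0.079 and PER3 at −0.91 ± 0.10. For immediate early genes and MAPK feedback, 9 rose and 7 fell of 22 tested genes (9 and 7), with IER3 at 1.37 ± 0.062, SPRY2 at 0.83 ± 0.052 and JUN at −0.57 ± 0.049. For ATF4 and the amino acid response, 13 rose and 5 fell of 25 tested genes (14 and 6), with ATF3 at 0.85 ± 0.12 and PSAT1 at −0.32 ± 0.049. For the interferon response, 8 rose and 5 fell of 22 tested genes (8 and 5), with IFIT2 at 0.77 ± 0.056 and OAS3 at −0.73 ± 0.084. For mesenchymal transition, 8 rose and 7 fell of 23 tested genes (8 and 7), with SERPINE1 (plasminogen activator inhibitor) at −0.91 ± 0.050. For mesenchymal basal markers, 5 rose and 7 fell of 16 tested genes (5 and 7), with CAV2 at 0.58 ± 0.051.

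Smaller or balanced changes were found elsewhere in MDA-MB-231. In mitosis 8 rose and 6 fell of 22 tested genes (8 and 7), with PLK1 at 0.42 ± 0.045 and CCNA2 at −0.36 ± 0.042. In the unfolded protein response 3 rose and 8 fell of 18 tested genes (3 and 8), with PDIA4 at −0.34 ± 0.036. Of the p53 targets, 4 rose and 5 fell of 22 tested genes (4 and 5). In fatty acid synthesis 3 rose and 7 fell of 15 tested genes (3 and 7), with ACACA at −0.44 ± 0.046, and in cholesterol synthesis 3 rose and 5 fell of 23 tested genes (3 and 5). Of the cytochrome P450 enzymes, 5 rose and 4 fell of 17 tested genes (5 and 5), with their electron donor POR at 0.43 ± 0.058. Of the estrogen response list, 2 rose and 2 fell of 23 tested genes (1 and 2), and of the histones, 1 rose and 0 fell of 10 tested genes (1 and 0). Of the epithelial and luminal lists, 6 rose and 2 fell of 22 tested epithelial genes (4 and 2) and 6 rose and 3 fell of 16 tested luminal genes (6 and 3), with KRT8 at 0.40 ± 0.042, KRT19 at −0.66 ± 0.078 and GATA3 at 0.53 ± 0.071. Several members of those lists, such as CDH1 at 0.599 ± 0.122 and 1.73 ± 1.27 CPM, lie at the level of the trace of MCF7 transcripts, which was highest in the first CO library.

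**Figure D2:**
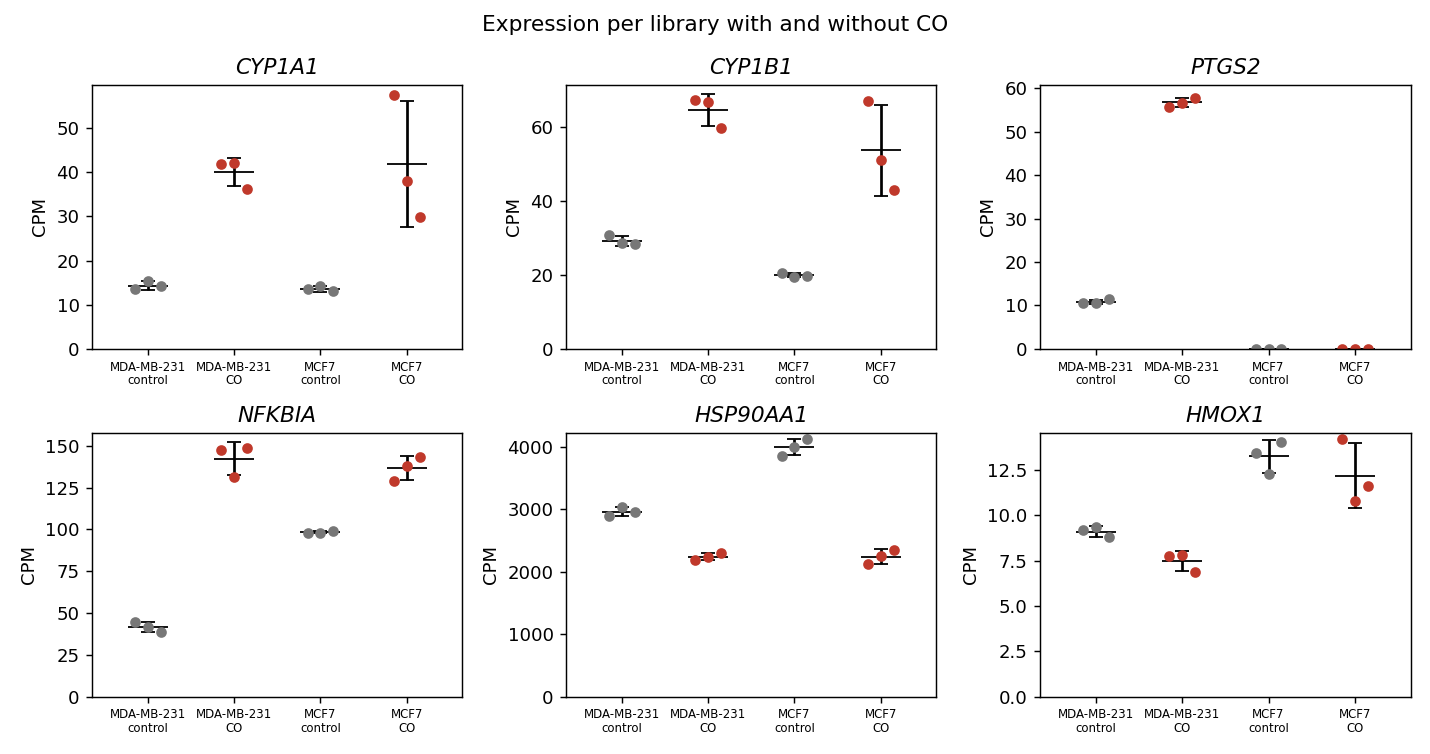
CPM per library of 6 genes on linear axes that start at 0. Points are single libraries (grey, control; red, CO), and black lines show the mean and SD of 3 libraries. CYP1A1 and CYP1B1 were higher with CO in both lines, PTGS2 rose in MDA-MB-231 and had a mean of 0.0288 CPM in the MCF7 control group, and HSP90AA1 was lower with CO in both.

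In MCF7, ALPP rose from 4.60 ± 0.565 to 15.1 ± 1.73 CPM, a log2 fold change of 1.71 ± 0.12. The proapoptotic gene BMF (chromosome 15, 40380091 to 40401085) rose from 6.83 ± 0.234 to 21.6 ± 4.21 CPM, a log2 fold change of 1.66 ± 0.13. PTGES, which encodes prostaglandin E synthase, rose by 1.64 ± 0.20, the membrane protein gene EMP1 by 1.56 ± 0.23, and SAT1, the polyamine-acetylating enzyme, by 1.37 ± 0.078. CAB39L rose by 1.31 ± 0.080. CYP1A1 (chromosome 15, 75011883 to 75017877), the classic target of the aryl hydrocarbon receptor, rose from 13.6 ± 0.615 to 41.8 ± 14.2 CPM (1.62 ± 0.23), and CYP1B1 from 19.9 ± 0.542 to 53.7 ± 12.3 CPM (1.43 ± 0.14). By the rule for named genes, the largest falls were in the IGF-like family gene IGFL1 (chromosome 19, 46733009 to 46734500), from 16.8 ± 0.586 to 4.79 ± 0.699 CPM, and in MAMDC4, at −1.70 ± 0.12. The neuropeptide precursor gene VGF was at −1.40 ± 0.085, and keratin 17 (KRT17, chromosome 17, 39775692 to 39780882) fell from 118 ± 6.21 to 46.4 ± 5.54 CPM. Transgelin (TAGLN), the cancer-testis antigen gene PRAME, the chloride channel gene CLIC3 and LOC338651 were at −1.26, −1.10, −1.10 and −1.08. Adjusted p of these 16 genes lay between 4.96e-14 (KRT17) and 4.67e-04 (CYP1A1), and KRT17 and ALPP have near-identical copies.

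As in the other line, many genes changed by small amounts. Of 14803 genes, 5872 passed the threshold in MCF7, 3103 higher and 2769 lower. At least 1.5-fold changes were found for 1008 of them, 639 higher and 369 lower, and at least 2-fold changes for 302. The 3 CO libraries lay on one side of the 3 control libraries for 49.1% of genes, where chance gives 10%. Leaving out single libraries gave 4953 to 5444 calls, and 4825 were made without the pair of libraries with the most reads of the other line.

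Heat shock genes formed the most uniform group in MCF7, in which 0 of 19 tested members rose and 17 fell (0 and 17 adjusted over the list alone). HSP90AA1 (chromosome 14, 102547075 to 102606086), the inducible cytosolic HSP90, went from 3993 ± 132 to 2241 ± 116 CPM, and FKBP4 and AHSA1, both HSP90 cochaperones, and the collagen chaperone gene SERPINH1 were at −0.94 ± 0.044, −0.59 ± 0.037 and −0.94 ± 0.053 (camera adjusted p = 2.12e-15, and adjusted p = 0.0519 with an estimated correlation). Of the circadian clock genes 12 of 18 tested members rose and 1 fell (12 and 1 adjusted over the list alone), with PER1 at 1.00 ± 0.077, NR1D2 at 0.66 ± 0.053, TEF at 0.81 ± 0.068 and PER3 at 0.61 ± 0.079 (adjusted p = 2.05e-05, and adjusted p = 0.0852 with an estimated correlation). Of the hypoxia-response genes 15 of 24 tested members rose and 1 fell (16 and 1 adjusted over the list alone), with the glucose transporter gene SLC2A1 at 0.46 ± 0.037, the histone demethylase gene KDM3A at 0.65 ± 0.057, MXI1 at 0.69 ± 0.087 and HK2 at 0.35 ± 0.045 (adjusted p = 2.05e-05, and adjusted p = 0.313 with an estimated correlation). Of the aryl hydrocarbon receptor targets 6 of 12 tested members rose and 1 fell (6 and 1 adjusted over the list alone), with the retinaldehyde dehydrogenase gene ALDH1A3 at 1.31 ± 0.10, NQO1 at 0.28 ± 0.034 and AHRR at 0.70 ± 0.11 (adjusted p = 0.00658, and adjusted p = 0.313 with an estimated correlation). Without the first MCF7 CO library 7 lists were called in place of 4, with DNA replication (0.0257), MYC and ribosome biogenesis (0.0151) and cholesterol synthesis (0.0132) added.

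Lists that camera did not call in MCF7 again held individual changes. HMOX1 stood at 13.3 ± 0.913 and 12.2 ± 1.78 CPM, with an adjusted p of 0.303, or 0.0466 without the first CO library. In the NRF2 and antioxidant list 9 rose and 6 fell of 23 tested genes (13 and 6), with GCLC, a glutathione synthesis enzyme, at 0.50 ± 0.047, G6PD at −0.61 ± 0.049 and the ferritin genes FTH1 and FTL at −0.36 ± 0.037 and −0.29 ± 0.033. For heme synthesis, transport and breakdown 6 rose and 4 fell of 23 tested genes (6 and 4), with ferrochelatase (FECH) at 0.59 ± 0.058, ABCB6 at −0.52 ± 0.056 and ALAS1 at 0.25 ± 0.050. For iron handling 4 rose and 5 fell of 16 tested genes (6 and 5), with ACO1 at −0.58 ± 0.067. For NF-kB and cytokines 6 rose and 1 fell of 19 tested genes (6 and 1), with NFKBIA at 0.48 ± 0.052 and RELB at 0.70 ± 0.13. For cholesterol synthesis 11 rose and 6 fell of 23 tested genes (12 and 6), with HMGCS1, HMGCR and SQLE, enzymes of the mevalonate and squalene steps, at 0.58 ± 0.046, 0.50 ± 0.044 and 0.40 ± 0.040, and TM7SF2 at −0.63 ± 0.052. For fatty acid synthesis 2 rose and 6 fell of 15 tested genes (2 and 6), with the desaturase genes FADS1 and FADS2 at −0.72 ± 0.041 and −0.38 ± 0.042. For mesenchymal transition 1 rose and 7 fell of 23 tested genes (1 and 7), with TGFB2 at −0.79 ± 0.066 and TPM1 at −0.46 ± 0.038. For invasion and organ metastasis 5 rose and 5 fell of 26 tested genes (5 and 5), with ID3 at −0.82 ± 0.054, L1CAM at −0.72 ± 0.049 and the collagenase gene MMP13 at 1.86 ± 0.17. MMP13 was not among the largest rises by the rule for named genes, so it missed the rule's minimum level or its separation of libraries. For immediate early genes and MAPK feedback 10 rose and 6 fell of 22 tested genes (10 and 7), with JUN at −0.64 ± 0.058 and ZFP36 at −0.60 ± 0.068.

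In DNA replication 5 rose and 10 fell of 25 tested genes (5 and 10), with POLA1 at −0.59 ± 0.069 and MCM3 at 0.24 ± 0.037. In the MYC and ribosome biogenesis list 3 rose and 11 fell of 26 tested genes (3 and 11), with MYC at 0.22 ± 0.044 and SRM at −0.38 ± 0.046. Of the mitosis genes 8 rose and 2 fell of 22 tested genes (8 and 2), with BIRC5 at 0.31 ± 0.045, and of the p53 targets 7 rose and 6 fell of 22 tested genes (8 and 6), with FDXR at −0.47 ± 0.078. The ATF4 list, in which 5 rose and 6 fell of 25 tested genes (6 and 8), included AARS at −0.54 ± 0.037 and SLC3A2 at 0.32 ± 0.036. The unfolded protein response list, in which 3 rose and 7 fell of 18 tested genes (5 and 7), included CALR at −0.31 ± 0.034 and DNAJC3 at 0.39 ± 0.052. The interferon list, in which 1 rose and 6 fell of 22 tested genes (1 and 5), included OAS3 at −0.69 ± 0.071 and IRF7 at −0.63 ± 0.091. Among the estrogen response genes 4 rose and 8 fell of 23 tested genes (4 and 8), with NRIP1 at 0.46 ± 0.046 and SIAH2 at −0.37 ± 0.048, and among luminal markers 1 rose and 4 fell of 16 tested genes (1 and 4), with AGR2 at 0.60 ± 0.049. Among epithelial genes 4 rose and 3 fell of 22 tested genes (4 and 2), with ELF3 at 0.40 ± 0.053. Among the mesenchymal basal markers 6 rose and 2 fell of 16 tested genes (6 and 3), with CD44 at 0.87 ± 0.049 and ANXA1 at 0.61 ± 0.067. Among glycolytic genes 5 rose and 7 fell of 20 tested genes (5 and 7), with LDHA at 0.24 ± 0.030, and among oxidative phosphorylation genes 6 rose and 7 fell of 38 tested genes (6 and 7). Among the cytochrome P450 enzymes 6 rose and 1 fell of 17 tested genes (6 and 1), with CYP26B1 at −0.53 ± 0.10, and among the histones 4 rose and 0 fell of 10 tested genes (4 and 1), with HIST1H2BK at 0.48 ± 0.054.

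**Figure D3:**
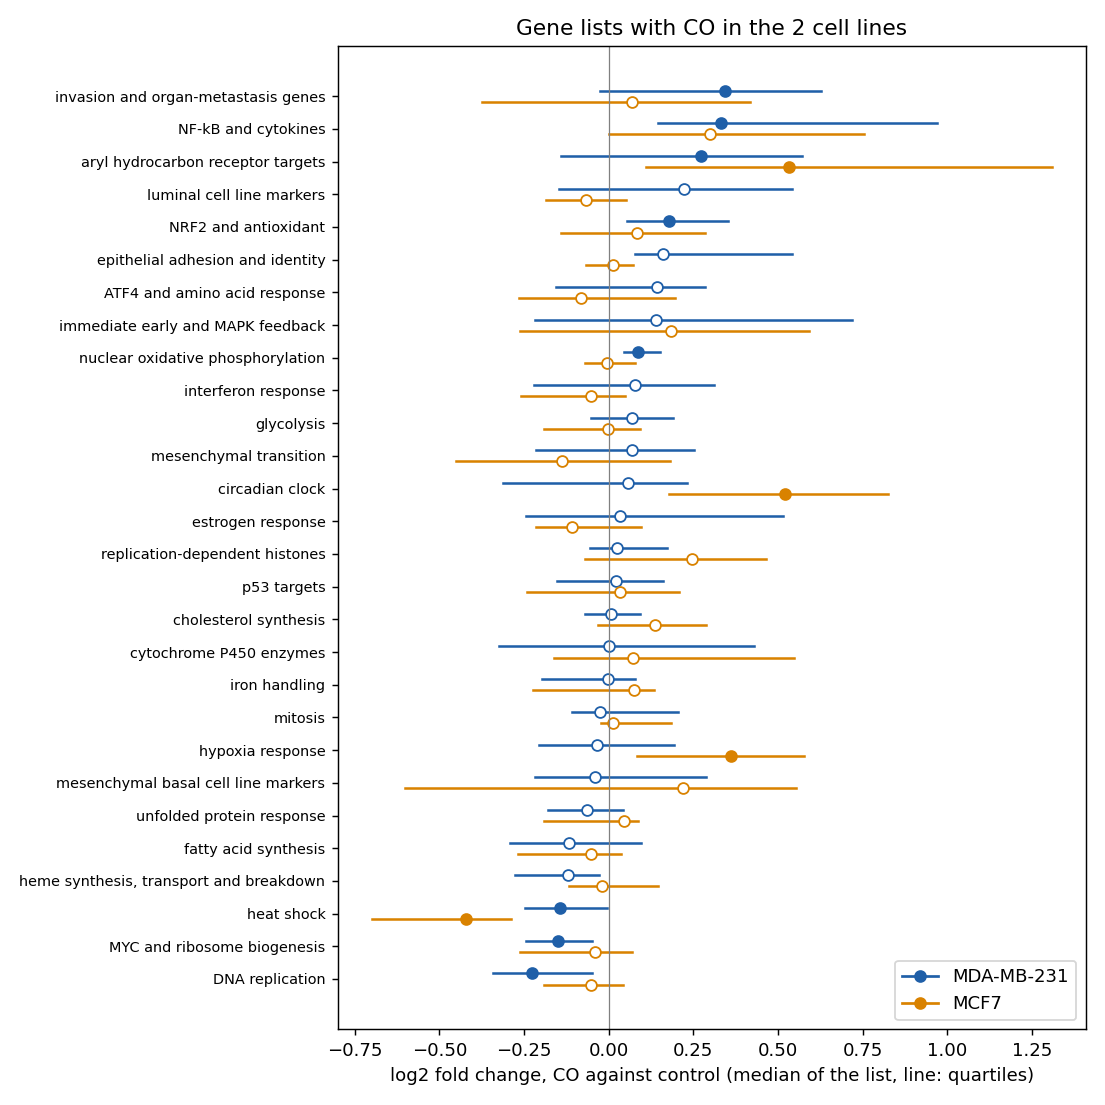
Median log2 fold change, CO against control, of the tested members of 28 gene lists in MDA-MB-231 (blue) and MCF7 (orange), with lines from the lower to the upper quartile of the members. Filled circles mark lists called by camera with the preset correlation (8 in MDA-MB-231 and 4 in MCF7), none of which was called with an estimated correlation. The heat shock list has its median at −0.14 in MDA-MB-231 and −0.42 in MCF7.

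Genes that changed in both lines tended to change in the same direction. Both lines called 1109 genes higher, where independent lists would share 694, and 1074 genes lower, where 608 would be shared (Fisher's exact test, p = 3.98e-83 and 1.58e-112 across genes, which are not independent replicates). Opposite calls numbered 368 (higher in MDA-MB-231) and 414 (higher in MCF7), against 620 and 681 for independent lists. Across the 9446 genes with a mean of at least 5 CPM in each line, the Pearson correlation of log2 fold changes was 0.32 and the Spearman correlation 0.28, and over all 14803 genes tested they were 0.15 and 0.21. ALPP was among the 8 largest rises in both lines by the rule for named genes, and CYP1A1 (1.48 in MDA-MB-231) and CYP1B1 rose in both. The responses of these genes did not pass the test of a difference (adjusted p = 0.0723, 0.812 and 0.296). XYLB was lower in both, at −1.53 and −0.998, with a difference of −0.54 ± 0.19.

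**Figure D4:**
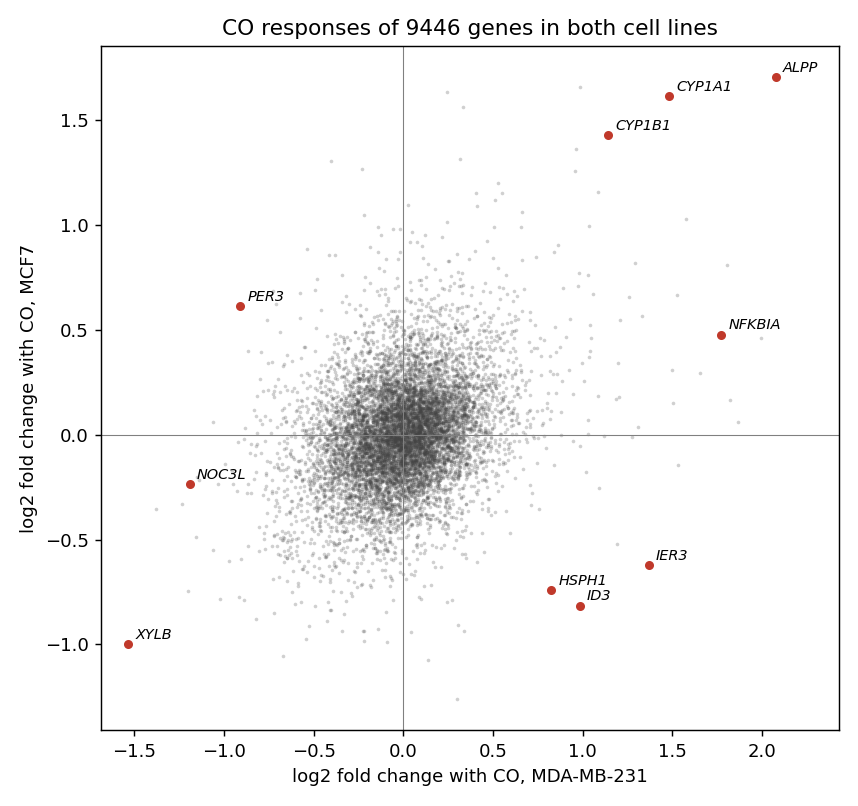
Log2 fold change with CO in MDA-MB-231 (horizontal axis) and MCF7 (vertical axis) of the 9446 genes with a mean of at least 5 CPM in each line, one point per gene. Labelled red points are a selection of the genes named in the text. The correlation across these genes is 0.32 (0.15 over all 14803 genes tested), with ALPP at 2.08 and 1.71, and IER3 at 1.37 and −0.62.

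The size of the response differed between the lines for many genes. The interaction called 4810 of 14803 genes, 2349 with a more positive and 2461 with a more negative response in MDA-MB-231. This share of positive differences, 48.8%, was 36.0% when libraries were scaled by total counts in place of TMM. Among genes with a mean of at least 5 CPM over the 12 libraries, the largest negative differences included FBXO32, a muscle and FOXO-linked ubiquitin ligase gene. FBXO32 went from 0.892 ± 0.177 to 3.78 ± 0.621 CPM in MCF7 and stood at 52.7 ± 2.26 and 49.5 ± 3.80 CPM in MDA-MB-231. CORO2B, ANKRD33B and the sodium channel gene SCN5A also responded more positively in MCF7, by −2.11 ± 0.39, −2.04 ± 0.24 and −2.01 ± 0.23 on the log2 scale (MDA-MB-231 minus MCF7), with CORO2B past the threshold in the counts and not in FPKM values with a pseudocount of 1 (adjusted p = 0.0522, and 0.0632 without a filter). With the same minimum, the 5 largest positive differences were in TLR4, PTGS2, RELN, RHOJ and KCTD15, and the largest negative one in PKP1. Each involves a group in which all 3 libraries were at 0 in the line that barely expresses the gene. TLR4, for example, went from 57.9 ± 2.61 to 116 ± 6.15 CPM in MDA-MB-231 and stood at 0.0923 ± 0.0900 and 0 CPM in MCF7. A fitted difference against libraries at 0 depends on the prior count and is no bound. These 6 calls were lost when single libraries were left out. The adjusted p became 0.0758 for TLR4 without the third MCF7 control library, and 0.0762 for KCTD15 without the first MDA-MB-231 CO library. It became 0.0972, 0.101 and 0.0512 for PTGS2 without the first or the third MCF7 control or the second MCF7 CO library, and 0.0547 for RELN without that CO library. For RHOJ it was 0.240, 0.0655, 0.0714 and 0.0627 without the first MCF7 control and the first, the second and the third MCF7 CO libraries. For PKP1 it was 0.259, 0.0546, 0.0810, 0.0813 and 0.0801 without the second and the third MDA-MB-231 control and the first, the second and the third CO libraries.

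When only the 11352 genes with at least 1 CPM in 3 or more libraries of each line were tested, a choice made after the data were seen, 4808 genes differed. Among those with a mean of at least 5 CPM over the 12 libraries, the largest positive differences were in KRT17, RAB17, ITGA10, HR and IER3. In that fit KRT17 differed by 2.34 ± 0.24 and IER3, an immediate early survival gene, by 2.00 ± 0.095. IER3 went from 390.5 ± 31.7 to 1008 ± 62.3 CPM in MDA-MB-231 and from 69.2 ± 4.67 to 45.1 ± 3.35 CPM in MCF7. With the same minimum of 5 CPM, the largest negative differences in that fit were in FBXO32, ANKRD33B, SCN5A, ALDH1A3 (−1.69 ± 0.19) and BIRC3 (−1.63 ± 0.24). Several genes of this set were still low in MDA-MB-231 or MCF7. In MDA-MB-231, HR went from 0.299 ± 0.0952 to 1.23 ± 0.206 CPM and KRT17 from 1.21 to 2.40 CPM. In MCF7, SCN5A went from 0.841 to 1.89 CPM and BIRC3 from 0.890 to 2.30 CPM. The CO libraries alone can meet the filter, as they did for HR in MDA-MB-231.

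At the level of gene lists the responses differed for 8 of 28. The heat shock list responded less negatively in MDA-MB-231, with a median difference of 0.34 (camera adjusted p = 4.18e-08, and adjusted p = 0.302 with an estimated correlation). ID3 (1.80 ± 0.091) and TNC (1.27 ± 0.20) belong to the invasion and organ-metastasis list, which differed with a median of 0.34 (adjusted p = 0.0118, and adjusted p = 0.380 with an estimated correlation). The NRF2 and ATF4 lists also responded more positively in MDA-MB-231, by medians of 0.14 and 0.16 (adjusted p = 0.00332 and 0.0118, and adjusted p = 0.380 and 0.575 with an estimated correlation). The oxidative phosphorylation list did so by 0.071, with adjusted p = 0.0287, which rose to 0.170 without TMM, 0.0806 without the third MDA-MB-231 control, 0.0526 without the second MDA-MB-231 CO and 0.0829 without the second MCF7 CO library, and adjusted p = 0.686 with an estimated correlation. Circadian clock genes, such as PER3 at −1.53 ± 0.13, hypoxia-response genes, such as HK2 at −1.08 ± 0.064, and DNA replication genes, such as RFC3 at −0.82 ± 0.078, responded more negatively in MDA-MB-231. Their median differences were −0.50, −0.25 and −0.14 (adjusted p = 0.0115, 1.48e-04 and 6.63e-04, and adjusted p = 0.380, 0.380 and 0.465 with an estimated correlation). NF-kB and cytokine genes as a list did not pass the test of a difference (adjusted p = 0.539), although NFKBIA itself differed (adjusted p = 1.19e-12). Nor did the aryl hydrocarbon receptor targets (adjusted p = 0.617).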

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

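The interaction test and the settings with total counts only were planned, and the tests of explanations and of other groupings of the libraries were chosen after the result was seen. The results listed first are given because the response to CO differed between the cell lines by the interaction test. That test called 4810 of 14803 genes. Of 177 genes named as examples of the lists, 133 differed, a share raised by their choice as the members with the smallest p.

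Among the genes named for MDA-MB-231, the interaction (MDA-MB-231 response minus MCF7 response, log2) was 3.69 for PRSS35, 3.15 for AKR1B1, 1.69 for CCL2, 1.53 for C7orf29 and 1.16 for ATOH8. In MCF7, AKR1B1 stood at only 0.412 and 0.170 CPM, within the trace of MDA-MB-231 transcripts, so its value is no measure of a difference in response. Genes that fell more in MDA-MB-231 gave −1.02 for CDCA7, −0.96 for NOC3L, −0.95 for FERMT1, −0.90 for TLN2, −0.67 for PCYOX1L, −0.54 for XYLB and −0.45 for SDSL. MYC moved in opposite directions (−0.53), and ALAS1 rose more in MDA-MB-231 (0.25). Among the genes named for MCF7 it was −1.39 for PTGES, −1.23 for EMP1, −0.999 for CAB39L, −0.67 for BMF and −0.40 for SAT1, and for the genes that fell there 2.33 for KRT17, 1.56 for TAGLN, 1.29 for VGF and 0.98 for CLIC3.

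Among genes with a mean of at least 5 CPM over the 12 libraries, the largest fitted interactions were in genes nearly silent in one of the lines. They were 5.08 for TLR4, 5.05 for PTGS2, 4.49 for RELN, 4.39 for RHOJ, 4.32 for KCTD15 and −4.46 for PKP1. Each of these 6 involves 3 libraries at 0, so that the value depends on the prior count and is no bound. FBXO32 (−2.15), CORO2B (−2.11), ANKRD33B (−2.04) and SCN5A (−2.01) completed the set.

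Of the lists, the median interaction was 0.34 for heat shock, 0.34 for invasion and organ metastasis, 0.16 for ATF4 and the amino acid response, 0.14 for NRF2 and antioxidant genes and 0.071 for oxidative phosphorylation. It was −0.50 for the circadian clock, −0.25 for the hypoxia response and −0.14 for DNA replication. With an estimated correlation none of these 8 lists was called (adjusted p = 0.302 to 0.686).

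Other groupings of the libraries were compared with the real one. For the interaction, the 60 groupings were the real one, the full exchange of CO and control in MCF7, and a random draw from the others. Counts out of 60 are therefore not shares of all possible groupings. As many genes were called in 2 of the 60 groupings, the real one included. The other one, with 6552 genes, exchanges CO and control in MCF7 and so adds the responses of the lines in place of subtracting them. For the 2183 genes called in both lines in the same direction, 1 of 60 groupings gave as many and the highest other, the same exchange, gave 782. Every grouping that mixed CO and control in both lines gave 0 genes in either count, so these groupings show only that CO and control libraries differ. They leave open whether chance makes the responses differ or coincide. For the 8 lists of the interaction, 7 of 60 groupings gave as many and the highest other gave 9. The groupings with 9 lists kept all MDA-MB-231 control libraries against all CO libraries of that line, and so held its full response. Some groupings that mixed CO and control in both lines reached 8 lists, but each still held part of the CO contrast. These groupings are therefore no clean measure of chance for lists, and chance cannot be excluded. Within a line 3 against 3 libraries make 10 groupings, too few for a share under 0.05. The real grouping gave 6563 genes in MDA-MB-231, 5872 in MCF7 and 12912 between the control lines, and the highest other gave 0 genes in each, so the real grouping was 1 of 10 each time. For lists, 3 of 10 groupings gave at least the 8 of MDA-MB-231 (highest other 8) and 8 of 10 at least the 4 of MCF7 (highest other 8).

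Genes specific to MCF7 were called higher with CO in MDA-MB-231, such as CDH1 (2.83-fold), FOXA1 (log2 fold change 1.43) and GRHL2 (log2 fold change 1.82), named after their values were seen. A rise caused by CO stays open, since the shares of the MCF7 level in the second and the third CO libraries, 0.110% and 0.146%, lay within or just above the controls (0.0923% to 0.135%), and 3 of the 41 genes were called without the first CO library. Reads or RNA carried over from MCF7 libraries remain a candidate explanation, since 87.8% of the 41 genes were highest in the first CO library among the 6 MDA-MB-231 libraries. The files hold no barcode or lane that would tell a mixture of RNA from a mixture of reads. The falls of ETS1 (−1.57) and TLR4 (−4.09) in MCF7 lie in the same range of traces.

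Chaperone mRNAs were lower and the cold-inducible RBM3 and CIRBP higher with CO, by 1.12 and 0.41 in MCF7 and 0.51 and 0.25 in MDA-MB-231. The choice of TMM over total counts did not matter here, since 17 heat shock genes were lower past the threshold in MCF7 with either. The TMM factors in MCF7 were 0.989 to 1.00 in control air and 1.01 to 1.02 with CO, so the 2 scalings are nearly alike. The comparison therefore says nothing about other effects of scaling. A lower temperature in the CO chamber cannot be told apart from CO, with 17 heat shock genes lower in MCF7 and 10 lower and 4 higher in MDA-MB-231, because no library was kept in air in that chamber. The heat-inducible HSPA1A, HSPH1 and DNAJB1, picked after their values were seen, were at 0.24, 0.83 and 0.10 in MDA-MB-231 and −0.80, −0.74 and −0.22 in MCF7. A response of the cells to CO is the biological explanation that the design gives, and it may account for the falls but stays untested.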

How the results depend on the processing

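The own-line filter and the removal of the 2 libraries with the most reads of the other line were tests chosen after the result was seen, and the other alternatives were planned. Over all alternatives, counts of genes or lists stayed within 1.5 times the reported count in 135 cases and left it in 9. For named genes, direction and side of the threshold were the same in 4852 cases, the call was lost in 56, gained in 1 and the sign changed in 2. For lists the numbers were 1114 the same, 30 lost and 32 gained.

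A minimum change of 1.5-fold gave 1226 genes in MDA-MB-231, 1008 in MCF7 and 1235 in the interaction, fewer by construction. The list calls rested on the inter-gene correlation. With a correlation estimated from the data camera called 0 lists in MDA-MB-231, 0 in MCF7 and 0 in the interaction, while fry called 15 lists in MDA-MB-231, 15 in MCF7 and 10 in the interaction. The cause was not tested for the estimated correlation, and fry asks another question. KCTD15 changed sign in the interaction, to −0.046 with FPKM and a pseudocount of 1, with and without the filter. With FPKM and a pseudocount of 0.1 it was 0.158, so the sign depended on the pseudocount. The cause of the smaller differences in FPKM than in counts was not tested.

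Leaving out each library in turn gave 5553 to 6051 genes in MDA-MB-231, 4953 to 5444 in MCF7, 4067 to 4755 in the interaction, 12742 to 12843 between the control lines and 1841 to 2149 called in both lines in the same direction. Lists numbered 6 to 8 in MDA-MB-231, 4 to 7 in MCF7 and 7 to 10 in the interaction. The value of 7 in MCF7 came without the first CO library, and the cause was not tested. Without the first MCF7 control library the MYC (0.0471) and interferon (0.0287) lists passed in the interaction, and without the first MCF7 CO library the interferon (0.0381) and cholesterol (0.0175) lists did.

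Over the other alternatives, the minimum change aside, the counts ranged from 5318 to 6713 in MDA-MB-231, 4825 to 6038 in MCF7, 3583 to 5341 in the interaction, 10354 to 13793 between the control lines and 1563 to 2288 for both lines in the same direction. DESeq2 called 6068, 5345, 4544 and 12677 genes in MDA-MB-231, MCF7, the interaction and the control lines. The share of higher genes moved with scaling. Total counts without TMM gave 44.4% higher in MDA-MB-231 (50.5% with TMM), 60.9% in MCF7 (52.8%) and 36.0% in the interaction (48.8%).

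With the own-line filter 6484 genes were called in MDA-MB-231, 5808 in MCF7 and 4808 in the interaction, and 7, 5 and 10 lists. The mesenchymal basal markers then passed in MCF7, with a median of 0.41 (camera adjusted p = 0.0137). They also passed in the interaction, with a median of −0.40 (0.0281), as did mesenchymal transition, with a median of 0.24 (0.0356). Heat shock was lost in MDA-MB-231 (0.0917). Without the 2 libraries with the most reads of the other line, 5318, 4825 and 3583 genes were called, and 8, 4 and 9 lists. With the replicate number as a replicate block the counts were 6672, 6038, 4942 and 12167, with 8, 4 and 8 lists and 2288 genes in both lines. Deviations from the group mean correlated by 0.00296 to 0.0377 between control and CO libraries of the same number. Between libraries of different numbers the correlation ran from −0.0901 to 0.0624. These values leave open whether the numbers pair the samples.

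Depth limits the genes near silence in one line. At 20534996 to 24388319 counts per library, a level of 0 CPM means that no count was seen, not that the RNA was absent, and the interactions of TLR4, PTGS2, RELN, RHOJ, KCTD15 and PKP1 rest on such libraries.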

Other observations

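The FOXO list test was written before its result was seen, and the other tests in this part were chosen after the result was seen.

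Genes that rose in MCF7 included FBXO32 (2.06), BMF (1.66) and TNFSF10 (2.20), the last chosen after its values were seen and low, at 0.0749 ± 0.0520 and 0.371 ± 0.158 CPM. These are known targets of FOXO transcription factors, which growth factor signalling through AKT holds outside the nucleus. In MDA-MB-231, TNFSF10 also rose, by 0.76, and its response did not differ past the threshold (edgeR adjusted p = 0.0727). BMF differed by −0.67 (MDA-MB-231 minus MCF7), and FBXO32 was at −0.089 in MDA-MB-231. It was hypothesized that other FOXO targets rise too, and a list of 20 such genes without FBXO32, BMF and TNFSF10 was tested. In MCF7, 12 rose and 0 fell past the threshold (edgeR), with a median log2 fold change of 0.39 and a camera p of 0.000204 (adjusted p = 0.00148 with the fixed lists added, and p = 0.0555 with an estimated correlation). Among them KLHL24 was at 0.99, CCNG2 at 0.95, BCL6 at 0.82 and TXNIP at 0.68. In MDA-MB-231, 10 rose and 3 fell (median 0.22, camera p = 0.00289, and p = 0.109 with an estimated correlation), and the interaction test of the list gave p = 0.356. Higher FOXO activity may thus be part of the response in MCF7, and these values do not show it to be particular to that line. The hypothesis rests on a preset correlation with which other groupings of the libraries also gave list calls.

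CYP1A1 and CYP1B1 rose in both lines, at 1.62 and 1.43 in MCF7 and 1.48 and 1.14 in MDA-MB-231. Reads carried over from the other line are argued against, since the largest amount they could add was 0.670% of the rise. Activation of the aryl hydrocarbon receptor stays open, since over both lines 9 of 20 tests of the other members of the receptor target list were higher past the threshold and 3 were lower. AHRR rose by 0.67 in MDA-MB-231 and 0.70 in MCF7, whereas ALDH1A3 was at −0.40 and 1.31. Whether the gas or the chamber led to it cannot be told apart, because 0 libraries had air in the same chamber.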
